A study of Homo sapiens with 6 samples.

How the data were processed

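RNA was sequenced from PC-9 cells, a human lung adenocarcinoma line whose growth depends on mutant EGFR. One population stably expressed a short hairpin RNA (shRNA) against IFITM3 (called shIFITM3 here) and the other a control shRNA (shControl), per the labels. The columns of the count table call the control ShEV, and whether it was a control hairpin or an empty vector is not settled by the sources used here. Per the labels, 3 biological replicates were taken for each of these 2 conditions, giving 6 samples. Total RNA was isolated with a column kit and libraries were made with the Illumina Stranded mRNA Prep, which keeps messenger RNA and marks the strand, per the labels' protocols. The number and the sequence of the hairpins are not given in the sources used here.

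The authors deposited raw read counts per gene for all 6 samples in one table, with 26485 gene symbols and no normalization. Per the submitters' processing notes, the tools were FastQC 0.12.1, fastp 0.23.4, HISAT2 2.2.1, SAMtools 1.20 and featureCounts from Subread 2.0.6, on genome build hg38. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart. In the exons of GENCODE release 29, 16 of 133 genes (those named by the rule given in this section and members of lists added later) overlapped an exon of another tested gene, 2 of them on the same strand. Total deposited counts were 21342028, 77228760 and 27493145 in shControl replicates 1, 2 and 3, and 21965506, 22872255 and 23852371 in shIFITM3 replicates 1, 2 and 3. A count of 0 in one library allows up to 3 counts, which is 0.0388 CPM (counts scaled to library size) in the deepest library and 0.141 CPM in the shallowest. Such limits cover counting error only and take counts as independent. The highest counts of list members too low to be tested were mostly even, so counts may come in pairs. The limits would then be too low.

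The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr with its default settings by group were kept (14018 genes), and 7251 symbols had no count in any sample. Libraries were scaled by TMM, with factors between 0.995 and 1.006. Each gene was fitted with glmQLFit on group alone and tested two-sided with glmQLFTest, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. A gene is said to rise, fall or change only where it passed that threshold. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 samples, and log2 fold changes are shIFITM3 against shControl. Standard errors (SE) were taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F. Counts of genes changed at least 2-fold use an absolute log2 fold change of 1 or more. One tested gene was left out of the printed tables.

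Gene symbols were placed with a RefSeq table of GRCh38.p14, the same assembly as hg38. Of the symbols, 23758 were current in RefSeq, 1562 were older symbols that matched 1 gene, and 1165 were unmatched. Coordinates are gene start and end on that assembly. All 13 mitochondrial protein-coding genes of a list meant as an RNA quality check had no row in the table, so no mitochondrial share was computed.

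Before the data were examined, the test, the named-gene rule and 33 gene lists were fixed from textbook knowledge. The lists cover interferon response, receptor, PI3K-AKT and MAPK signalling, cell cycle, metabolism, stress, epithelial and mesenchymal state, other cell types and RNA quality. Of their members, 676 distinct genes were tested and 112 were too low to be tested. The 31 lists with at least 3 tested members were compared with all other tested genes by camera (limma 3.58.1, preset inter-gene correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over those lists. Camera was repeated with the correlation estimated from the residuals, and fry was run as a test of each list by itself. The counts of members that rose and fell were also computed adjusted over the list alone. The 2 ways of counting gave the same numbers in 26 of the 32 lists with a tested member, and the other values are given beside each list.

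The genes named are IFITM3, IFITM1 and IFITM2, EGFR, MET, AKT1 and AKT2, the 8 largest rises and 8 largest falls by log2 fold change, and up to 4 members of each list with the smallest p. The largest changes were taken among genes with adjusted p under 0.05, an average log2 CPM of at least 2 and no overlap in CPM between the groups, leaving out symbols of non-coding, antisense and unnamed loci. Some genes that the rule takes are not reported here. Genes outside this rule are named in a few places and were then chosen after their values were seen.

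Other settings tried were RLE, upper-quartile and total-count scaling, no filter, a strict filter of at least 50 counts in at least 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a 1.5-fold change, and leaving out each sample in turn. A further pair was chosen after seeing the data: thinning shControl replicate 2 to the mean depth of the other 5 samples, and offsets for GC content and gene length. Replicates of a group were compared before averaging. A chi-square of their counts was 2.84 to 5.14 per degree of freedom, so every pair differed by more than the sampling noise of independent counts.

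The scripts were tested on simulated data drawn with the means and depths of these samples. After the filter 13864 simulated genes were tested, among them 200 changed genes and 23 more raised 1.2-fold as a list. Far fewer genes were changed there than passed in the data, so its recovery rates need not hold for the data. The edgeR test recovered 13 of those 23, 66% of the genes changed 1.25-fold, 78% of those changed 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 11 of its 193 calls (5.70%) were unchanged genes. Sequence searches used GENCODE release 29 transcripts, in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.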

Results

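The data were whole-transcriptome read counts from PC-9 cells with stable knockdown of IFITM3, an interferon-induced membrane protein that restricts virus entry through endosomes, and from control cells, with 3 samples in each group. The comparison asks what the loss of IFITM3 changes in an EGFR-mutant lung cancer line, and the study's title sets it in the context of the MET receptor, the AKT pathway and resistance to osimertinib, an inhibitor of mutant EGFR. No drug treatment of these samples is named in the labels. Depth was 21342028, 77228760 and 27493145 total counts in shControl replicates 1, 2 and 3, and between 21965506 and 23852371 in the shIFITM3 replicates.

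IFITM3 (chromosome 11, 319676 to 320860, GRCh38) fell to 0.183 times its control level in the knockdown. Its level was 57.0, 60.5 and 62.8 CPM in shControl replicates 1, 2 and 3 (1209, 4659 and 1720 counts), and 10.4, 12.9 and 9.75 CPM in shIFITM3 replicates 1, 2 and 3 (228, 296 and 233 counts). The means were 60.1 ± 2.91 and 10.99 ± 1.65 CPM (SD, n = 3 each), a log2 fold change of -2.45 with an SE of 0.079 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.97e-18). The levels thus go with the labels of all 6 samples. The neighbouring paralogs were expressed far lower. IFITM1 (chromosome 11, 314040 to 315272) was at 1.34 ± 0.232 CPM in shControl and 0.712 ± 0.176 CPM in shIFITM3, a log2 fold change of -0.90 (SE 0.334, edgeR adjusted p = 0.025). That call ended when shControl replicate 2, shControl replicate 3, shIFITM3 replicate 1 or shIFITM3 replicate 3 was left out, with adjusted p of 0.0554, 0.0969, 0.0753 and 0.0962. IFITM2 (chromosome 11, 307816 to 309395) was at 0.471 ± 0.144 and 0.542 ± 0.183 CPM (edgeR adjusted p = 0.59). Reads of these near-identical genes are hard to assign, so the 2 paralog values are uncertain. In the list of IFITM paralogs 0 of 3 tested members rose and 1 fell. Its median log2 fold change was 0.18, its mean -0.14 and its camera direction downwards (adjusted p = 0.845).

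Knockdown cells differed from control cells across much of the transcriptome. Of 14018 tested genes, 7870 (56.1%) passed the threshold, 3885 of them higher and 3985 lower in shIFITM3 (edgeR adjusted p under 0.05). Most of these changes were small, with a median absolute log2 fold change of 0.372. The 914 genes that changed at least 2-fold were mostly rises, 677 against 237 falls. In a test against a 1.5-fold change 1115 genes passed, 807 higher and 308 lower. The samples of a group lay close together. Across genes, log2 CPM of samples of the same group correlated at r = 0.992 to 0.995, and of different groups at 0.971 to 0.975. In 8531 genes (60.9%) the CPM ranges of the groups did not overlap, where chance gives 10%.

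**Figure D1:**
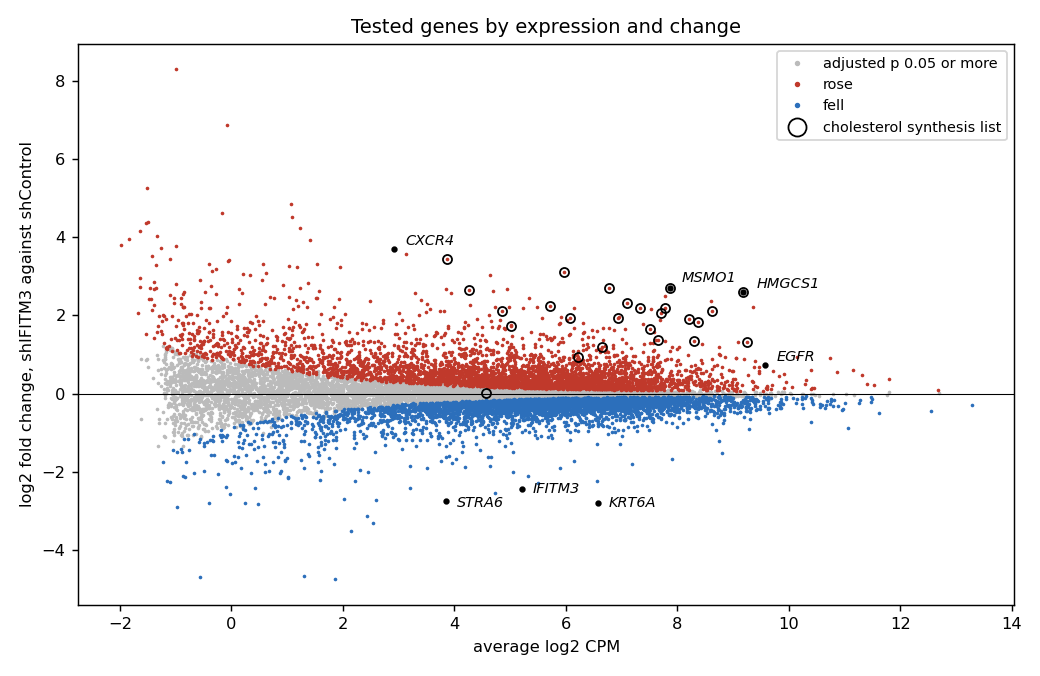
Log2 fold change (shIFITM3 against shControl) of each tested gene by its average log2 CPM, with genes that rose in red, genes that fell in blue and other genes in grey. Open circles mark the 25 members of the cholesterol synthesis list, 24 of which rose.

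Among genes with an average log2 CPM of at least 2, the largest rise was that of CXCR4 (chromosome 2, 136114349 to 136118149), the receptor of the chemokine CXCL12, from 1.29 ± 0.341 to 16.2 ± 1.60 CPM (log2 fold change 3.72, SE 0.160, edgeR adjusted p = 1.5e-15). PIK3IP1 (chromosome 22, 31281593 to 31292534), an inhibitor of PI3 kinase, went from 1.57 ± 0.128 to 18.5 ± 1.19 CPM, a log2 fold change of 3.57. KISS1 (chromosome 1, 204190341 to 204196491), which encodes the kisspeptin peptides, rose from 5.85 ± 1.17 to 47.5 ± 1.26 CPM (3.03 on the log2 scale). FILIP1L (chromosome 3, 99828811 to 100114501) rose by 2.69 (SE 0.0876). Also among the 8 largest rises were STARD4 (3.45), INSIG1 (2.71) and MSMO1 (2.70), which act in sterol metabolism. The largest fall was that of PKP1 (chromosome 1, 201283506 to 201332989), a desmosome protein of stratified epithelia, from 7.08 ± 1.37 to 0.609 ± 0.227 CPM (log2 fold change -3.52, SE 0.238, edgeR adjusted p = 7.54e-12). KANK4 (chromosome 1, 62236165 to 62319434) and the glutamate transporter gene SLC1A6 (chromosome 19, 14950033 to 15010643) had log2 fold changes of -3.33 and -3.14. The basal keratins KRT6A, KRT6B and KRT5 on chromosome 12 had values of -2.81, -2.72 and -2.55. KRT6A went from 164 ± 3.36 to 23.3 ± 0.467 CPM, although KRT6A and KRT6B are near-identical and their separate values are uncertain. STRA6 (chromosome 15, 74179466 to 74212259), a receptor for retinol uptake, went from 22.7 ± 1.75 to 3.41 ± 0.492 CPM (-2.75), and the retinoid-induced gene RARRES1 (chromosome 3, 158696892 to 158732457) from 5.89 ± 0.625 to 0.913 ± 0.2304 CPM (-2.69). Each of these genes had an edgeR adjusted p of 1.29e-10 or less.

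**Figure D2:**
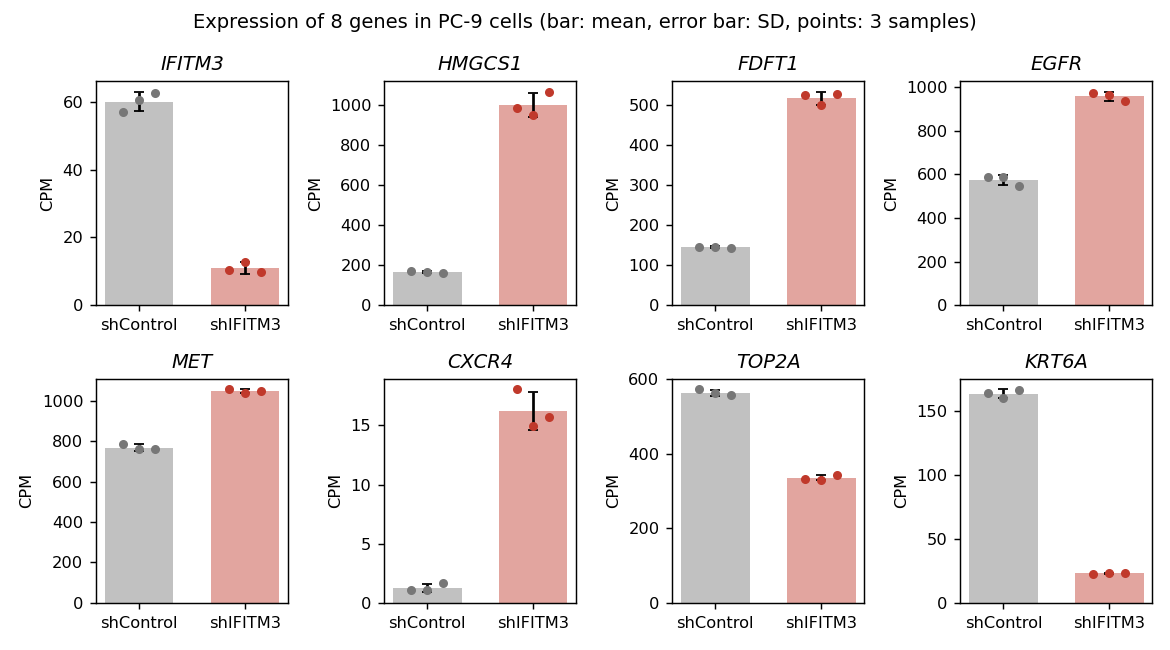
CPM of IFITM3, HMGCS1, FDFT1, EGFR, MET, CXCR4, TOP2A and KRT6A in shControl (grey) and shIFITM3 (red), each axis starting at 0. Bars are means of 3 samples, error bars are SD and points are single samples. In each of the 8 genes the samples of the groups do not overlap, as for IFITM3 with 57.0 to 62.8 CPM against 9.75 to 12.9 CPM.

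The receptor genes that give the study its setting were more abundant in knockdown cells. EGFR (chromosome 7, 55019017 to 55211628) rose from 575 ± 23.4 to 958 ± 20.7 CPM, a log2 fold change of 0.74 (SE 0.0306, edgeR adjusted p = 7.54e-16). MET (chromosome 7, 116672196 to 116798377) rose from 768 ± 15.7 to 1047 ± 8.56 CPM, a log2 fold change of 0.45 (SE 0.0264, edgeR adjusted p = 5.99e-13). Of 22 tested genes of receptor tyrosine kinases, their ligands and their regulators 11 rose and 4 fell, among the rises ERBB3 (0.78), the EGFR ligand gene HBEGF (1.54, from 25.1 ± 1.70 to 73.6 ± 4.12 CPM) and the AXL ligand gene GAS6 (0.84). The list's median log2 fold change was 0.17, which passed camera (adjusted p = 0.00318) but not with an estimated correlation (adjusted p = 0.16).

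AKT1 (chromosome 14, 104769349 to 104795748) was at 190 ± 5.60 and 204 ± 10.9 CPM (log2 fold change 0.10, edgeR adjusted p = 0.0351). This small difference missed the threshold under upper-quartile scaling (adjusted p = 0.084), after GC and length correction (0.816), and without shControl replicate 1, shControl replicate 3, shIFITM3 replicate 2 or shIFITM3 replicate 3 (0.136, 0.063, 0.231 and 0.0521). AKT2 (chromosome 19, 40230317 to 40285345) was at 163 ± 4.19 and 156 ± 2.29 CPM (-0.07, edgeR adjusted p = 0.0924), and passed under upper-quartile scaling (0.0385) and after GC and length correction (0.000504). Of 34 tested PI3K-AKT pathway members 17 rose and 9 fell (10 fell adjusted over the list alone). GAB2 (1.28), PIK3CD (1.72) and IRS2 (0.82), which carry the signal from receptors to PI3 kinase or belong to it, rose. So did the lipid phosphatase gene INPP4B (0.81), a negative regulator, while PHLPP1 (-0.75), a phosphatase gene that also acts against the pathway, fell. INPP4B and PHLPP1 were chosen after their values were seen. The list as a whole did not pass camera (median 0.08, adjusted p = 0.057). It passed with total-count scaling (0.0493), with no filter (0.0273) and without shControl replicate 2 (0.0425).

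Of 20 tested targets of FOXO factors, which AKT holds out of the nucleus when active, 14 rose and 0 fell (16 rose adjusted over the list alone). The list's median log2 fold change was 0.59, higher than other genes (camera adjusted p = 1.21e-08, and 0.032 with an estimated correlation). KLF6 (1.44, from 48.8 ± 0.727 to 133 ± 4.99 CPM) and CITED2 (1.45) rose most in it, and ERBB3 and IRS2 rose too. ERBB3 is also counted in the receptor list and IRS2 in the PI3K-AKT list, so the FOXO list is not a separate readout. BCL6 (-0.11), SESN2 (0.07) and SESN1 (-0.04) were among the 6 targets that did not pass. MAPK output genes also rose, 16 of 23 with 3 falls and a median of 0.47 (camera adjusted p = 1.87e-05, and 0.0457 with an estimated correlation). LIF rose by 0.96 and IER3 by 0.70, both also members of the list of inflammatory NF-kB targets. The ERK phosphatase genes DUSP5 and DUSP6 rose by 0.94 and 1.05. The immediate early genes FOS (-0.57) and EGR1 (-0.35) and the receptor gene EPHA2 (-0.29) were the 3 falls.

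The list with the smallest camera p was cholesterol synthesis and uptake, where 24 of 25 tested genes rose and 0 fell. The median log2 fold change was 2.07, and the list stood apart from other genes (camera adjusted p = 1.76e-158, and 0.0112 with an estimated correlation). HMGCS1 (chromosome 5, 43287470 to 43313412), which makes the precursor of mevalonate, rose from 165 ± 3.54 to 1000.2 ± 59.7 CPM (log2 fold change 2.60, SE 0.0373, edgeR adjusted p = 3.98e-24). MSMO1 (chromosome 4, 165327669 to 165343164) rose from 62.8 ± 3.77 to 409 ± 16.9 CPM and FDFT1 (chromosome 8, 11795582 to 11839298), the squalene synthase gene, from 145 ± 2.56 to 518 ± 16.1 CPM. STARD4 (chromosome 5, 111496033 to 111512535), a sterol carrier, rose from 2.62 ± 0.600 to 29.4 ± 1.60 CPM, and INSIG1 (chromosome 7, 155297878 to 155310235), which retains the SREBP machinery in the endoplasmic reticulum when sterols are plentiful, from 29.7 ± 2.10 to 194 ± 14.5 CPM. PMVK was the one member that did not pass (0.02, edgeR adjusted p = 0.819).

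Fatty acid synthesis genes followed, with 11 of 14 higher and 2 lower (12 higher adjusted over the list alone). The median was 0.48 (camera adjusted p = 2.42e-16, and 0.032 with an estimated correlation). The desaturase gene SCD rose from 126 ± 12.96 to 654 ± 24.6 CPM (2.37), ACSS2 by 1.97, FADS2 by 1.89 and FADS1 by 0.95. FADS1 and FADS2 overlap on opposite strands. ELOVL6 (-0.62) and SREBF1 (-0.32), which encodes an activator of these genes, fell.

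**Figure D3:**
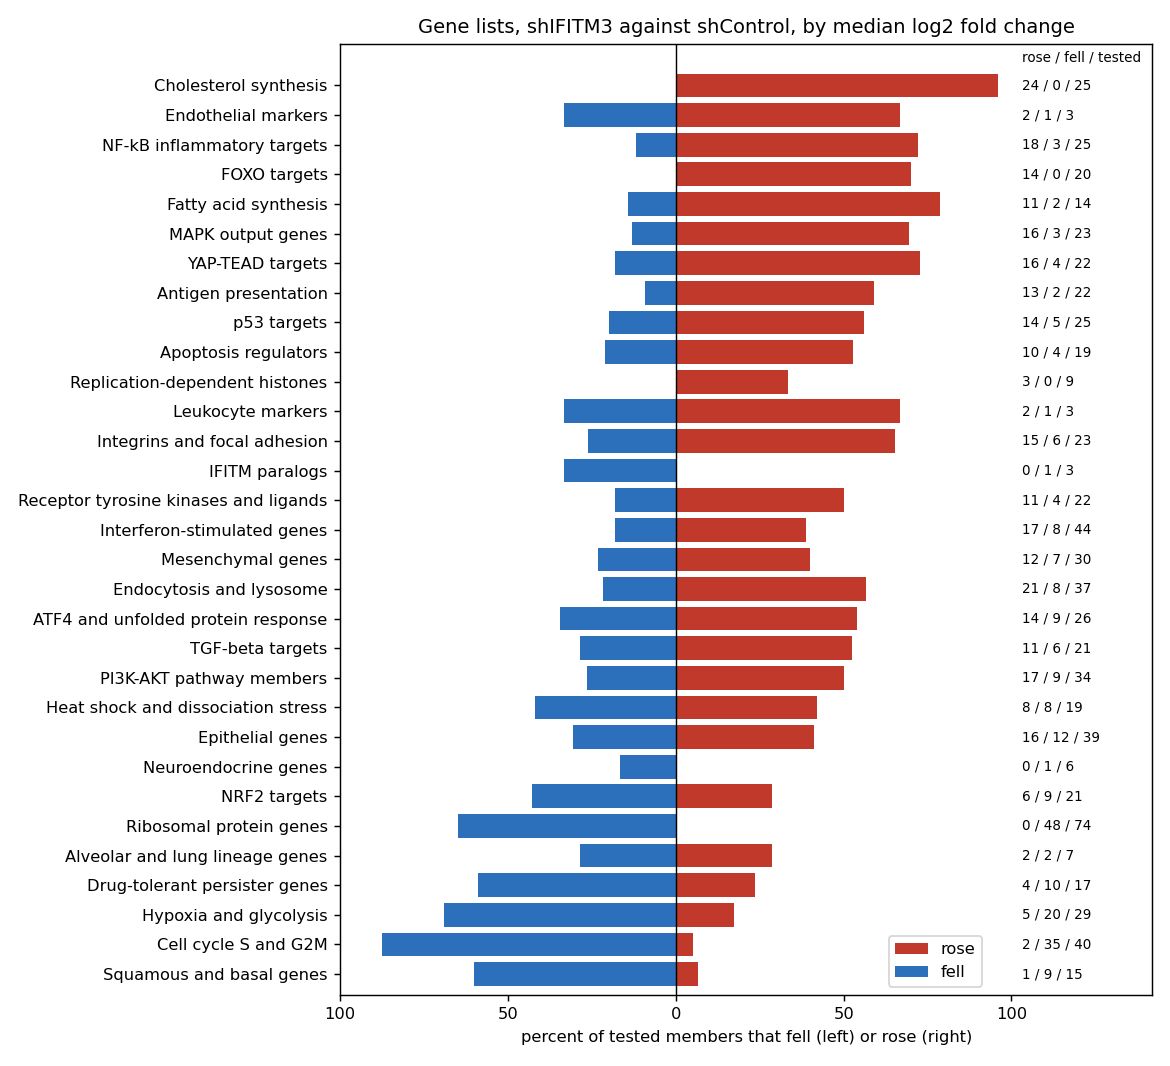
Percent of tested members of each gene list that fell (blue, left) or rose (red, right) in shIFITM3, ordered by median log2 fold change, with the numbers that rose, fell and were tested at the right. Cholesterol synthesis stands at the top with 24 of 25 members higher, and the cell cycle list near the bottom has 35 of 40 members lower.

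Proliferation genes went down. Of 40 tested genes of DNA replication and mitosis 35 fell and 2 rose, with a median log2 fold change of -0.44 (camera adjusted p = 5.98e-17, and 0.0112 with an estimated correlation). TOP2A (chromosome 17, 40388525 to 40417896) fell from 563 ± 8.16 to 335 ± 6.99 CPM (-0.75, SE 0.0298, edgeR adjusted p = 3.17e-16). KIF20A (-0.86), BUB1B (-0.84) and TPX2 (-0.58), all acting in mitosis, fell as well. The 2 rises were E2F1 (0.24) and CENPE (0.22). Among p53 targets 14 of 25 rose and 5 fell. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 27.7 ± 2.24 to 75.3 ± 1.61 CPM (1.46). MDM2 (0.74), FAM210B (0.91) and TNFRSF10B (0.61) also rose. The list's median was 0.26 (camera adjusted p = 0.00816), and its call was lost with an estimated correlation (adjusted p = 0.108). Of 19 apoptosis regulators 10 rose and 4 fell (11 rose adjusted over the list alone). The inhibitor of apoptosis genes BIRC3 (1.69) and BIRC2 (0.80) and the pro-survival gene MCL1 (0.45) rose, and so did PMAIP1 (0.84), whose product promotes death. The list's camera adjusted p was 0.0501, at the threshold. It came under 0.05 with total-count scaling (0.0465), no filter (0.0156), the GC and length correction (0.0368) and the thinned library (0.0488), and without shControl replicate 1, 2 or 3 or shIFITM3 replicate 2 (0.0315, 0.0425, 0.0486 and 0.0497).

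Inflammatory NF-kB targets were higher, 18 of 25 with 3 lower and a median of 0.68 (camera adjusted p = 7.69e-07, adjusted p = 0.11 with an estimated correlation). TRAF1 rose from 3.09 ± 0.609 to 18.5 ± 1.35 CPM (2.58), RELB from 15.1 ± 2.27 to 46.9 ± 3.45 CPM (1.67) and BIRC3 from 34.7 ± 4.99 to 110 ± 6.01 CPM, while TNFAIP2 fell from 236 ± 7.68 to 124 ± 2.61 CPM (-0.93). Antigen presentation genes rose in 13 of 22 cases and fell in 2, among them HLA-E (0.76), HLA-B (0.71), TAPBP (0.72) and the MHC class I transactivator gene NLRC5 (1.51, from 12.2 ± 0.183 to 34.7 ± 2.97 CPM). Their median was 0.27 (camera adjusted p = 0.00329, adjusted p = 0.0809 with an estimated correlation), and reads may be shared among HLA genes. Interferon-stimulated genes, the family to which IFITM3 belongs by regulation, were split. Of 44 tested members 17 rose and 8 fell, and the list did not stand apart (median 0.16, camera adjusted p = 0.647). LGALS3BP rose (0.62, from 267 ± 7.26 to 410 ± 20.8 CPM), whereas OAS3 (-0.47) and SAMD9 (-0.76) fell.

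Adhesion genes changed in both directions. The collagen receptor gene ITGA2 rose from 232 ± 17.9 to 1084 ± 37.2 CPM (2.23), within a list of 23 integrin and focal adhesion genes of which 15 rose and 6 fell. ITGB5 (0.52) rose, and the laminin genes LAMC1 (-0.63) and LAMA5 (-0.55) fell (list median 0.19, camera adjusted p = 0.00185, adjusted p = 0.0809 with an estimated correlation). YAP-TEAD targets rose in 16 of 22 cases and fell in 4 (median 0.38, camera adjusted p = 1.18e-05, adjusted p = 0.0809 with an estimated correlation). ANKRD1 (1.94), CTGF (1.62) and NT5E (1.18) rose, whereas IGFBP3 fell from 662 ± 23.0 to 229 ± 9.52 CPM (-1.53). TGF-beta targets rose in 11 of 21 cases and fell in 6 (7 adjusted over the list alone). PMEPA1 (0.89), CTGF and BHLHE40 (1.09) were among the rises. Their median was 0.10 (camera adjusted p = 0.00184), and the call was lost with an estimated correlation (adjusted p = 0.169) and in limma-voom (adjusted p = 0.0695).

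Mesenchymal genes (12 of 30 rose, 7 fell, median 0.14, camera adjusted p = 0.197) and epithelial genes (16 of 39 rose, 12 fell, median 0.04, camera adjusted p = 0.6) did not pass as lists. VIM rose from 10.3 ± 0.643 to 26.8 ± 2.37 CPM (1.39), FN1 by 1.00 and CALD1 by 0.63. VIM shares exon sequence with an antisense gene. CLDN1 (1.66) and PRSS8 (1.08) rose, while the epithelial transcription factor gene ELF3 fell from 59.3 ± 2.55 to 10.9 ± 1.31 CPM (-2.45) and KRT8 by 0.50 on the log2 scale. KRT8 overlaps KRT18 on the opposite strand.

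Markers of squamous and basal epithelium fell, 9 of 15 with 1 rise and a median of -0.61 (camera adjusted p = 3.7e-06, and 0.0487 with an estimated correlation). KRT6A, KRT5, KRT6B and PKP1, already named among the largest falls, led the list. DSC3 was the 1 rise (3.39, from 0.205 ± 0.142 to 2.10 ± 0.356 CPM). Alveolar and lung lineage genes (2 of 7 rose, 2 fell, median -0.10, camera adjusted p = 0.6) and neuroendocrine genes (0 of 6 rose, 1 fell, camera adjusted p = 0.845) did not pass as lists. FOXA1 (-0.65), FOXJ1 (-1.99) and SCG2 (-1.23) fell, and ABCA3 (0.52) and CAV1 (0.12) rose. For the neuroendocrine list the median (0.04) was above 0, while the mean (-0.0037) and the camera direction were below it.

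Hypoxia and glycolysis genes were lower, 20 of 29 with 5 higher and a median of -0.31 (camera adjusted p = 1.09e-05, adjusted p = 0.0573 with an estimated correlation). The glucose transporter gene SLC2A1 fell from 510 ± 4.58 to 334 ± 6.20 CPM (-0.61), LDHA from 2270 ± 59.6 to 1705 ± 29.01 CPM (-0.41), GAPDH from 6952 ± 108.4 to 5102 ± 141 CPM (-0.45) and the oxygen-dependent prolyl hydroxylase gene EGLN3 by 1.02 on the log2 scale. The list of ATF4 and unfolded protein response genes went both ways, with 14 of 26 higher and 9 lower (median 0.13, camera adjusted p = 0.555). STC2 (1.28) and the cystine transporter gene SLC7A11 (1.02) rose, and SLC7A5 (-0.88) and SLC3A2 (-0.59), the subunits of a large neutral amino acid transporter, fell. NRF2 targets also went both ways, with 6 of 21 higher and 9 lower (median -0.03, camera adjusted p = 0.134). AKR1B10 fell from 226 ± 7.12 to 64.9 ± 5.76 CPM (-1.80) and AKR1C2 by 0.90 on the log2 scale, and TXNRD1 rose (0.47). AKR1C2 has near-identical relatives, so its value is uncertain. Without shControl replicate 2 this list passed camera downwards (adjusted p = 0.0391), with a median of 0.0018.

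Endocytosis and lysosome genes, which include the compartment where IFITM3 resides, rose in 21 of 37 cases and fell in 8 (median 0.14, camera adjusted p = 0.0275, adjusted p = 0.169 with an estimated correlation). The sialidase gene NEU1 rose from 15.03 ± 0.377 to 47.3 ± 1.40 CPM (1.66), RAB5B by 0.83, the lysosomal cholesterol exporter gene NPC1 by 0.76 and the proton pump gene ATP6V0D1 by 0.65. Genes linked to drug-tolerant persister cells fell in 10 of 17 cases and rose in 4 (median -0.30, camera adjusted p = 0.012, adjusted p = 0.108 with an estimated correlation). IGFBP3 and TPX2 were among the falls, and CD44 (0.92, from 1188 ± 37.3 to 2247 ± 23.9 CPM) and ALDH1A3 (0.60) among the rises.

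Of 74 ribosomal protein genes 0 rose and 48 fell (50 adjusted over the list alone), by a median of only -0.10 that stayed between -0.12 and -0.09 under the other scalings (camera adjusted p = 0.00101, adjusted p = 0.245 with an estimated correlation). RPS28 had the largest of the values named (-0.94), beside RPL12 (-0.29), RPL3 (-0.25) and RPS2 (-0.31). RPS28 overlaps KANK3 on the opposite strand. Heat shock and dissociation stress genes rose in 8 of 19 cases and fell in 8 (median 0.07, mean 0.08, camera downwards with adjusted p = 0.949). DNAJB1 rose (0.59), and DNAJA1 (-0.56), HSP90AA1 (-0.30) and HSPH1 (-0.34) fell. Replication-dependent histone genes rose in 3 of 9 cases and fell in 0 (median 0.23, camera adjusted p = 0.195). The 3 were HIST1H1C (1.30), HIST1H2BD (1.03) and HIST1H2AC (1.11), members of a family with near-identical copies.

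Most markers of cell types other than epithelium were too low to be tested. Of 14 leukocyte markers 3 were tested, with CSF1R at 0.922 ± 0.364 and 4.40 ± 0.298 CPM (2.40) and CD68 (0.20) higher and LAPTM5 (-0.84) lower in shIFITM3 (list median 0.20, camera adjusted p = 0.6). Of 8 endothelial markers 3 were tested, with KDR at 0.348 ± 0.237 and 2.69 ± 0.238 CPM (3.03) and CDH5 (1.68) higher and PECAM1 (-1.66) lower (list median 1.68, camera adjusted p = 0.6). COL1A1 was the one tested marker of 10 for fibroblasts, at 9.56 ± 0.841 and 11.5 ± 1.74 CPM (0.29, edgeR adjusted p = 0.0381). That call ended in DESeq2 (0.0567), after GC and length correction (0.141), and without shControl replicate 2 (0.163), shControl replicate 3 (0.093) or shIFITM3 replicate 3 (0.28).

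Across the 31 lists tested, 17 passed camera, 12 upwards and 5 downwards. Some lists share members, so these are not all separate findings. The MAPK and NF-kB lists share LIF and IER3, and the FOXO and receptor lists share ERBB3. With an estimated correlation 6 passed: cholesterol synthesis, fatty acid synthesis, FOXO targets and MAPK output genes upwards, and cell cycle and squamous and basal genes downwards. The labels name one knockdown and one control population, and p-values measure the spread between the replicates of each.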

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

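The thinning of the deepest library and the GC and length correction were chosen after seeing the data. Calls of single genes and of lists were not compared for the test against a 1.5-fold change, nor calls of lists for DESeq2. IFITM3 kept its call under each alternative in which single genes were compared, with a log2 fold change between -2.37 and -2.58. The number of changed genes was 7434 (DESeq2) to 8082 (no filter) over the other scalings, filters, tools and corrections, and 7124 to 7553 with 1 sample left out, and 0 shared genes turned sign. Upper-quartile scaling lowered the share of rises from 49.4% to 46.4%. The test against a 1.5-fold change, which asks for larger effects, left 1115. The strict filter, which tests fewer genes, left 609 genes changed at least 2-fold, 143 of them falls, in place of 914 and 237. Of the 17 lists passing camera, 6 passed with an estimated correlation. That form also tests on the few residual degrees of freedom of 6 samples. A lost call is therefore no evidence by itself of shared variation within a list. Fry, which does not compare a list with other genes, passed 28. Over the settings compared, 16 calls of named genes were lost and 2 gained, those of IFITM1, AKT1, AKT2 and COL1A1, and no result reversed. Camera calls of 4 lists (PI3K-AKT, apoptosis, TGF-beta and NRF2) changed under some setting. Same-numbered samples did not deviate together (correlations 0.016, 0.033 and 0.0063), and not every sample correlated best with its own number. With the replicate block 7870 genes changed, 7739 of them shared with the 7870 without it. COL1A1 then missed the threshold (adjusted p = 0.0537), the apoptosis list passed (0.0325) and no other named call changed. Depth limits what can be said of low genes, where a count of 0 allows up to 0.141 CPM in the shallowest library if counts are independent.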

Other observations

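The tests of library composition and of the spread between samples and the heptamer search were chosen only after the results they bear on were seen. The GC content and length test, the LXR and retinoid gene lists, the test on other splits of the samples, the copy number test and the share of falls with a heptamer were written down before their own values were seen. Some genes outside the naming rule were close to absent in control cells and present in knockdown cells, and were chosen after their values were seen. TNF (chromosome 6, 31575565 to 31578336), which encodes the inflammatory cytokine, had counts of 0, 0 and 0 in the shControl replicates. The shIFITM3 replicates had 26, 16 and 42. Against 3 counts over the 3 control libraries this is at least 50.9-fold higher, a bound that takes counts as independent. TNF was the 1 changed gene with no count in any shControl library, and 0 changed genes had no count in any shIFITM3 library. With TNF at that bound the median of the NF-kB list stays at 0.68. RCSD1 had counts of 2, 0 and 0 against 52, 55 and 58, and FAM89A 0, 0 and 2 against 12, 21 and 20. NOS3, the endothelial nitric oxide synthase gene, went from 0.191 ± 0.0862 to 5.09 ± 0.516 CPM (log2 fold change 4.52), and the cystatin gene CST1 from 0.191 ± 0.0799 to 5.08 ± 0.179 CPM (4.87). In the other direction, CASP14, a caspase of the outer epidermis, fell from 5.53 ± 0.953 to 0.201 ± 0.0955 CPM (-4.76), and the hypoxia gene CA9 from 3.82 ± 0.254 to 0.143 ± 0.0937 CPM (-4.68).

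Retinoid genes formed a further group. CRABP2, which carries retinoic acid to its receptor, fell from 152 ± 5.07 to 32.1 ± 2.72 CPM (-2.24), beside STRA6 and RARRES1. A hypothesis is that retinoid signalling was lower in knockdown cells. Of 8 other retinoid-responsive genes tested, 0 rose and 4 fell, with DHRS3 at -1.63, CYP26B1 at -1.41 and RARA at -0.50 among the falls. Their median was -0.49, and as a set they moved downwards by fry (p = 0.000136) and camera (p = 0.0323), though camera with an estimated correlation gave p = 0.0912. Fry passed 28 of the 31 lists fixed before the data were examined, lists that went both ways among them. A fry call therefore carries little weight here. The median and the camera result with the preset correlation go with the hypothesis but do not settle it. The other 4 genes did not pass, among them RARB (0.08, edgeR adjusted p = 0.901) and TGM2 (-0.04, edgeR adjusted p = 0.195). ALDH1A3, which encodes an enzyme of retinoic acid synthesis and was not in this set, rose (0.60).

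The rise of the sterol synthesis genes does not rest on how libraries were scaled, since the list's median was at least 2.05 under each of 3 other scalings. Correction for GC content and length, available for 100% of the 25 genes, left 0.992 of the median (2.07 before, 2.05 after), which argues against such a bias. One biological hypothesis is that knockdown cells sensed less sterol, which may also lower targets of LXR, the oxysterol receptors. Of 5 LXR targets tested 3 fell and 1, SMPDL3A, rose, with a median of -0.56. Fry, which passed 28 of the 31 lists fixed before the data were examined, says little by itself about these 5 targets. The set moved downwards by fry (p = 0.000921) but did not pass camera with a preset (p = 0.145) or an estimated correlation (p = 0.212), so this stays open, as do the knockdown itself and differences in culture. The real grouping gave a camera p of 5.68e-160 for the list, against 6.95e-08 as the smallest of the other splits. The 1 of 10 splits that reached the real value was the real grouping itself. The other splits mix the conditions, so they are no test of it. With 10 splits no share under 0.05 is possible.

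That 56.1% of the tested genes passed goes with a small spread between samples. The common dispersion was 0.00206 (a coefficient of variation of 4.54%), and 14.2% of the called genes also passed the test against a 1.5-fold change, so much of the count may reflect small differences measured precisely. Broad copy number differences between the populations are argued against as a main source. The local median of 50 neighbouring genes on each side was removed. The median absolute log2 fold change of the called genes was then slightly higher (0.369 before, 0.375 after, a percent reduction of -1.72). The largest local median was 0.224, against 0.198 in shuffled genes and 0.583 with a planted gain of 0.5. The percent reduction was not computed for the planted gain, and differences spanning few genes would be missed. The real grouping called 7870 genes and the highest of the other splits 0. The 1 of 10 splits that reached the real count was the real grouping itself, too few splits for a share under 0.05. The other splits mix the conditions, which adds the group difference to the spread, so their low counts are no test of the real grouping.

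Some of the falls may be off-target effects of the hairpin, since the seed of a guide against IFITM3 can also pair with other 3′ UTRs. Among 14437 heptamers in the 3′ UTRs of 12688 genes, adjusted for UTR length and GC content, ATGCTCA went most strongly with lower fold changes (1398 genes, mean difference -0.106, t = -6.29), and the lowest t in 20 shuffled runs was -4.26. It lies in IFITM3 with the overlapping GATGCTC (t = -6.06) and TGCTCAA (t = -5.29), within GATGCTCAA at chromosome 11, 320743 to 320751 (GRCh38, minus strand), coding sequence of exon 1 of the 2-exon transcript, while AATGCTC, which IFITM3 lacks, had t = -5.46. IFITM3 holds 1082 of the 14437 heptamers, and the 3 overlapping ones are not separate evidence. The set comparison found 20 of 20 planted effects of -0.2 log2, larger than the -0.106 seen here, but also called 3 of 20 shuffled runs. The hairpin sequence is not known here, so off-target pairing stays a candidate explanation. It does not cover all large falls: 68 of 212 genes that fell at least 2-fold carried 1 or more of the 3 heptamers (32.1%, exact 95% interval 25.8 to 38.8). That share was above those of all 12688 genes (21.6%) and of genes that rose at least 2-fold (19.1%), but the heptamers were picked on these same genes, so the excess is no test of the explanation.

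On the side of the rises, heptamers of the AU-rich element that marks short-lived messenger RNAs stood out. TATTTAT, in 4490 genes, went with a mean log2 fold change higher by 0.079 (t = 6.43), followed by ATATTTA (t = 5.34), TTATTTA (t = 4.62) and ATTTATT (t = 4.51). No explanation of this was tested.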
